A study of Mus musculus with 5 samples.

How the data were processed

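Messenger RNA levels were measured in back skin of hairless albino mice with 5 one-colour CodeLink oligonucleotide arrays. Each array carried Cy5-labelled material made from total RNA that had been extracted with Trizol, per the labels' protocols. The arrays fall into 5 groups of 1 array. They are wild-type (WT) skin without UVB, WT skin 3 h and 24 h after 1 kJ per square metre of UVB, and skin of Xpa mutants 3 h and 24 h after the same dose. Unirradiated Xpa mutant skin was not analysed here. Whether the RNA of an array came from a single mouse or a pool is not given in the sources used here.

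The deposited scanner tables hold, per the file headers, values quantified with CodeLink Expression Analysis 5.0.0.31312. For each of the 36227 spots of an array they give the mean intensity of the spot, the median intensity of its local background and a quality flag. In 180603 of 180603 spots that were not masked, the authors' raw intensity was within 0.01 of the spot mean minus the background median. The authors also deposited a normalized table. As read from its values, it holds background-subtracted intensity that was quantile normalized over all spots, with controls, and values of 0 or less set to 0.001. The values of the series' matrix were the same in 181135 of 181135 cells, so its probe identities, linear scale and direction follow from the scanner tables. Each of its columns had a median intensity of 46.26, no centring per gene was present, and which software normalized it is not given in the sources used here.

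The analysis started again from the scanner values. Background was corrected with limma 3.58.1 in R 4.3.3 (normexp model with saddle-point estimation and an offset of 50, fitted on all spots that were not masked). Of 34967 gene probes per array, 126 that were masked on any array and 98 with an irregular shape or a P flag on any array were left out, as were 640 fiducial, 320 negative control and 300 positive control spots. The remaining 34743 probes were quantile normalized between the 5 arrays and taken to log2. Each gene probe had 1 spot, so no averaging of spots was needed. A gene was represented by its brightest probe, by the mean log2 value over the 5 arrays. A probe counted as above background when the scanner software had not given it the low-signal flag. All further steps used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

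Probes were named through the platform annotation, which gave 1 gene symbol for 21471 of the kept probes and several for 678. Of those it did not list, 532 were named through a RefSeq accession in the GRCm38.p6 gene table and 12062 stayed unnamed here. No gene was named from a probe with several symbols. In all, 18466 genes had a symbol. The gene table was used for names and for which genes neighbour each other. No genome build is named for the arrays, so no coordinates are given.

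Signal over background limited the measurement. Between 23.5% and 25.2% of the gene probes of an array were above background, 4644 genes were above it on all 5 arrays, and 8088 on at least 1. The number of arrays limits the precision. With 1 array per group there was no test, standard error, p-value or replicate check, and a difference compares 2 arrays, not 2 conditions. Anything particular to an array, such as its animal, its piece of skin or its hybridization, cannot be told apart from its group. Spiked bacterial control probes give a view of technical noise only. Over 27 of them with 10 spots each, the spread between spots of a probe within an array had a median SD of 0.13 on the log2 scale, and the spread of a probe's mean between arrays was 0.07 after each array's shift was removed and 0.23 before. Those shifts ran from -0.31 on the WT array at 24 h to 0.27 on the Xpa mutant array at 24 h.

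The comparisons were WT at 3 h and at 24 h, each against WT without UVB, the Xpa mutant against WT at 3 h and at 24 h, and the difference between the last 2, which sets the change from 3 h to 24 h in the mutant against that in WT. A gene was compared when it was above background on at least 1 array involved, and counted as higher or lower at a log2 difference of at least 1 (2-fold). Where the dimmer array was below background, the fold is given as at least N-fold, the brighter array's value set against the higher of the dim probe's own value and the lowest value of a named gene above background on that array. The counts use the log2 difference itself. A counted gene can therefore have a bound under 2-fold, as Fosl1 did in WT at 3 h (at least 1.44-fold). No fold is given where both arrays were below background, and no value of the difference of changes for a gene below background on any of the 4 arrays.

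For 32 gene lists (pathways and markers of cell types that skin samples can hold) the median log2 difference over the members above background is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart outside percentiles 2.5 to 97.5. This is a description of these arrays, not a test, and a median needs at least 3 members. The T cell, melanocyte, red blood cell and sex-chromosome lists had fewer than 3 members above background in every comparison and have no median.

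The comparisons, lists, thresholds and the rule for naming genes were fixed before the data were examined. The rule names, in each comparison, 11 genes always (Xpa, Cxcl1, Cxcl2, Cxcl5, Cxcr2, Il1b, Il6, Tnf, Ptgs2, Cdkn1a and Mdm2). It adds the 6 highest and 6 lowest genes (5 and 5 for the difference of changes) among those with a plain symbol, above background on the brighter array, brighter than the median gene and of the same sign in the authors' deposited table. It also adds up to 3 members of each list, by size of difference. Genes named outside this rule are said to have been chosen after their values were seen.

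The procedure was tested on simulated data made from the spots of the unirradiated array, with 200 of 8816 probes changed in the place of the WT array at 3 h. Of 50 probes changed at each size, a difference of at least 2-fold in the right direction was read for 0 at 1.5-fold, 10 at 2-fold, 40 at 3-fold and 49 at 4-fold. The median log2 difference read back was 0.44, 0.85, 1.27 and 1.60, each smaller than the fold made. None of the 8616 unchanged probes reached 2-fold. The simulated arrays carried noise set for single spots, with no differences between animals, and only probes above background were scored. On the real arrays most genes past 2-fold were below background on an array involved. The simulation therefore gives no rate of false calls for the real arrays. Of 100 random lists of unchanged probes 6 lay outside percentiles 2.5 to 97.5, and of 20 lists of raised probes 20 lay above 97.5.

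The alternatives tried were no background correction, plain subtraction with a floor, median scaling and cyclic loess between arrays, the authors' deposited tables (floored at 1 before log2), other filters on dim probes, the mean over a gene's probes, thresholds of 1.5-fold and 3-fold, and random lists not matched on expression. Quantile normalization without the Xpa mutant array at 24 h, a filter for genes above background on every array compared, and list medians with dim genes at their bounds were chosen after seeing the data.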

Results

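Expression in back skin was profiled on 5 arrays, 1 per group, to follow WT hairless mice at 3 h and 24 h after UVB. Xpa mutants, which lack a nucleotide excision repair protein that binds damaged DNA, were set against WT at the same times. The series concerns the neutrophil chemoattractant Cxcl1 and UVB inflammation in these mutants. The number of gene probes above background was 8816 on the unirradiated WT array, 8456 and 8526 on the WT arrays at 3 h and 24 h, and 8234 and 8492 on the Xpa mutant arrays at 3 h and 24 h. Median local background lay between 92 and 94 intensity units on every array. Correlations between arrays, across the genes above background on all 5, ran from 0.89 to 0.97, the highest between the WT and mutant arrays at 3 h.

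The targeted gene, Xpa, was read first as a check of the labels. Its log2 level was 7.49 on the unirradiated WT array, 7.13 on the WT array at 3 h and 7.55 on the WT array at 24 h, against 6.64 and 6.42 on the mutant arrays at 3 h and 24 h. The probe was above background only on the unirradiated WT array and the WT array at 24 h, where it was at least 1.41-fold higher than on the mutant array of that time. The order of the 5 values followed the labels, but the position of the probe relative to the deletion is not known here, and at this level the check is weak.

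In WT skin 3 h after UVB, many chemokine, stress keratin, alarmin and early response genes were at least 2-fold higher on the array than without UVB, and some collagen genes were lower. The monocyte attractants Ccl7 and Ccl2 were at least 4.81-fold and 4.29-fold higher, Ccl20, which attracts Ccr6-bearing lymphocytes and dendritic cells, at least 4.58-fold, and the neutrophil attractants Cxcl1 and Cxcl2 at least 3.27-fold and 2.27-fold. Krt16, a keratin of activated epidermis, was 7.32-fold higher, and the transcription factor gene Junb at least 5.05-fold. The fibrillar collagen gene Col1a1 was 2.30-fold lower, and Col3a1 had a log2 difference of -1.32.

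Of 7147 genes compared, 162 were at least 2-fold higher and 90 lower, with a robust SD of all log2 differences of 0.32. For 112 of the higher and 79 of the lower genes the dimmer array was below background, so their bounds can lie under 2-fold. In the authors' deposited table the counts were 333 and 310, which moves the share of higher genes from 64.3% to 51.8%, and among genes above background on both arrays they were 50 and 11.

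Inflammatory groups stood apart in WT skin at 3 h. Of 16 chemokines outside the neutrophil-attracting CXC group, 8 were at least 2-fold higher and 0 lower, with a median log2 difference of 1.02 (percentile 100). With dim genes at their bounds the median was 0.58, and over genes above background on both arrays it was -0.04, since that filter leaves out chemokines that were dim without UVB. Among the 4 CXC members above background, 2 were higher and 0 lower (median 0.82, percentile 99.8). These medians were 0.12 and 0.10 and no longer stood apart with no filter on dim probes. Over 21 inflammatory cytokines and mediators 3 were higher (median 0.20, percentile 99.5): Icam1, the adhesion molecule that leukocytes bind, 5.17-fold, Il6 at least 2.59-fold, and Socs3, a feedback inhibitor of cytokine signalling, at least 3.71-fold. Il1b was at least 1.34-fold and Ptgs2, the inducible prostaglandin synthase, at least 1.13-fold higher, while Tnf, Cxcl5 and Cxcr2 were below background on both arrays. Among members above background on both arrays the median of the cytokines and mediators was -0.01. Macrophage markers had a median of 0.53 over 8 genes (percentile 100), with 1 at least 2-fold higher and 0 lower. Cd14 was at least 2.00-fold and the complement gene C1qc 1.61-fold higher.

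Epidermal stress genes formed the group with the highest median at 3 h. Among 22 stress keratins and alarmins 13 were at least 2-fold higher and 0 lower (median 1.31, percentile 100), including Krt16, the protease inhibitor Slpi (at least 4.45-fold) and the cornified envelope precursor Sprr2h (7.20-fold). Of 21 immediate-early genes 8 were higher and 0 lower (median 0.74, percentile 100), with Ier3 4.78-fold and Fosl1 at least 1.44-fold higher. Among 13 NRF2 and metallothionein genes 3 were higher (median 0.29, percentile 99.9). They were the metal-binding Mt1 and Mt2, 3.92-fold and 2.54-fold, and Srxn1, at least 1.25-fold. Heat shock genes had a median of 0.23 over 13 members (percentile 99.6), with only Hsp90aa1 past 2-fold, at 2.08-fold. Of 19 p53 targets 4 were higher and 1 lower (median 0.18, percentile 99.0). The apoptosis gene Pmaip1 was at least 2.48-fold, Plk2 2.36-fold, Btg2 2.24-fold and the cell cycle inhibitor Cdkn1a 2.07-fold higher, and Mdm2 was below background on both arrays. Without background correction the p53 median was 0.11 and no longer stood apart.

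Other tissue compartments also differed at 3 h. All 18 fibroblast and matrix markers were above background, 0 were at least 2-fold higher and 2 lower (median -0.41, percentile 0). Among 31 cornified layer genes 2 were higher, Krt2 at least 2.08-fold and Lce3c 2.42-fold, yet the median was -0.31 (percentile 0). Cell cycle genes had a median of -0.22 over 18 members (percentile 1.25) with 0 past 2-fold, and of -0.15, no longer apart, over those above background on both arrays. Hair follicle and hair keratin genes were higher, 7 of 13 by at least 2-fold and 0 lower (median 1.00, percentile 100). The median was 0.55 with dim genes at their bounds, and 0.26, no longer apart from random lists, over genes above background on all 5 arrays. The higher hair genes included the inner root sheath keratin genes Krt25, at least 6.40-fold, and Krt71, at least 2.56-fold. Beside them, skeletal muscle markers had a median of -0.10 (percentile 9.25) and adipocyte markers of -0.22 (percentile 2.62). The lowest genes were the olfactory receptor Olfr1179 (at least 8.71-fold), Sostdc1, an inhibitor of BMP and Wnt signals (2.19-fold), Pcdh10 (1.83-fold), Krt7 (1.98-fold), Ttbk2 (1.41-fold) and Mre11a, a DNA break repair nuclease (2.25-fold), all of them bounds.

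In WT skin 24 h after UVB, 17 of 23 stress keratins and alarmins were at least 2-fold higher than without UVB. The medians of the macrophage and p53 target lists lay above 0, and those of the muscle, adipocyte and fibroblast and matrix lists below. Krt6a and Krt16, keratins of activated epidermis, were 26.6-fold and 25.3-fold higher. The cornified envelope precursors Sprr2f, Sprr2e and Sprr2i were at least 10.4-fold, 8.86-fold and 6.70-fold higher, and Slpi at least 7.36-fold. Cxcl1 was at least 2.52-fold higher, while Cxcl2, Il1b, Il6, Tnf, Ptgs2, Cxcl5, Cxcr2 and Mdm2 were below background on both arrays.

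Of 7267 genes compared, 178 were at least 2-fold higher and 161 lower (robust SD 0.39). For 114 and 93 of these the dimmer array was below background. The authors' deposited table gave 400 and 398, and genes above background on both arrays 64 and 68.

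Among 23 stress keratins and alarmins 17 were at least 2-fold higher and 0 lower at 24 h (median 2.37, percentile 100). The 32 cornified layer genes split, with 5 higher and 5 lower and a median of -0.21 (percentile 0.46). The late envelope genes Lce3c and Lce3a were 4.84-fold and at least 4.14-fold higher, while Flg2, a filaggrin relative, was 5.28-fold and Lce1m 4.61-fold lower, as was the differentiation keratin Krt78, at 6.49-fold. Alox12e, an epidermal lipoxygenase, was at least 4.04-fold, the transcription factor gene Helt 5.81-fold and Olfr1179 at least 8.71-fold lower. Olfr1179 was above background only on the unirradiated array, so both comparisons rest on that spot, and a fault of the spot cannot be excluded. Cell cycle genes had a median of 0.24 over 21 members (percentile 99.0) with 0 past 2-fold. The mitotic gene Birc5 was 1.98-fold and Cdk1 1.88-fold higher.

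Macrophage markers were higher at 24 h, 5 of 9 by at least 2-fold and 0 lower (median 1.02, percentile 100). The complement genes C1qb and C1qc and the lysozyme gene Lyz2 were 2.43-fold, 2.40-fold and 2.40-fold higher. Of 13 other chemokines 5 were higher and 1 lower (median 0.65, percentile 100). Ccl7 and Ccl9 were at least 1.93-fold and 1.87-fold higher, and Ccl27a, made by keratinocytes to attract skin-homing T cells, was 3.47-fold lower. Of 3 CXC members 1 was higher, Cxcl1, and 1 lower, Cxcl15, and the median of 0.99 (percentile 99.8) is the value of Pf4, a platelet chemokine. With no filter on dim probes that median was -0.04, and that of the other chemokines 0.15 and no longer apart. Without genes that were below background before UVB, the median of the other chemokines was -0.04 at 3 h and -0.20 at 24 h, since that filter leaves out the chemokines seen only after UVB. Among 21 p53 targets 5 were higher and 0 lower (median 0.65, percentile 100), with Cdkn1a 2.10-fold, Dcxr at least 2.05-fold, Aen, an apoptosis nuclease, at least 1.53-fold and Sesn2 at least 1.43-fold higher. Of 19 nucleotide excision repair genes 2 were higher and 0 lower (median 0.06, percentile 70.4). They encode parts of the TFIIH complex, Gtf2h5, 5.26-fold, and Ccnh, at least 1.53-fold.

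Markers of deeper tissue were lower on the WT array at 24 h. Of 18 skeletal muscle markers 9 were at least 2-fold lower and 0 higher (median -1.03, percentile 0), including the myosin light chain Myl1 at 3.38-fold and the calcium buffer Pvalb at 2.85-fold. Adipocyte markers had a median of -0.54 over 11 genes (percentile 0.04), with Pck1 2.21-fold and the adipokine Adipoq 1.89-fold lower. Among 18 fibroblast and matrix markers 5 were lower and 0 higher (median -0.43, percentile 0.02), with Col1a1, Col1a2 and Col3a1 3.18-fold, 3.08-fold and 3.04-fold lower.

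The WT comparisons shared genes. Among 6799 genes compared in both, 55 were at least 2-fold higher at both times, where independent lists would share 1.72 and unchanged arrays simulated against the same control 0.70. For lower genes the overlap was 23, against 2.13 and 1.02. The simulation drew normal noise at the robust SDs, which rarely reaches 2-fold, and left out larger errors such as those of dim probes. It therefore cannot bound the overlap that the shared unirradiated array gives, and part of the excess may come from that array.

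**Figure D1:**
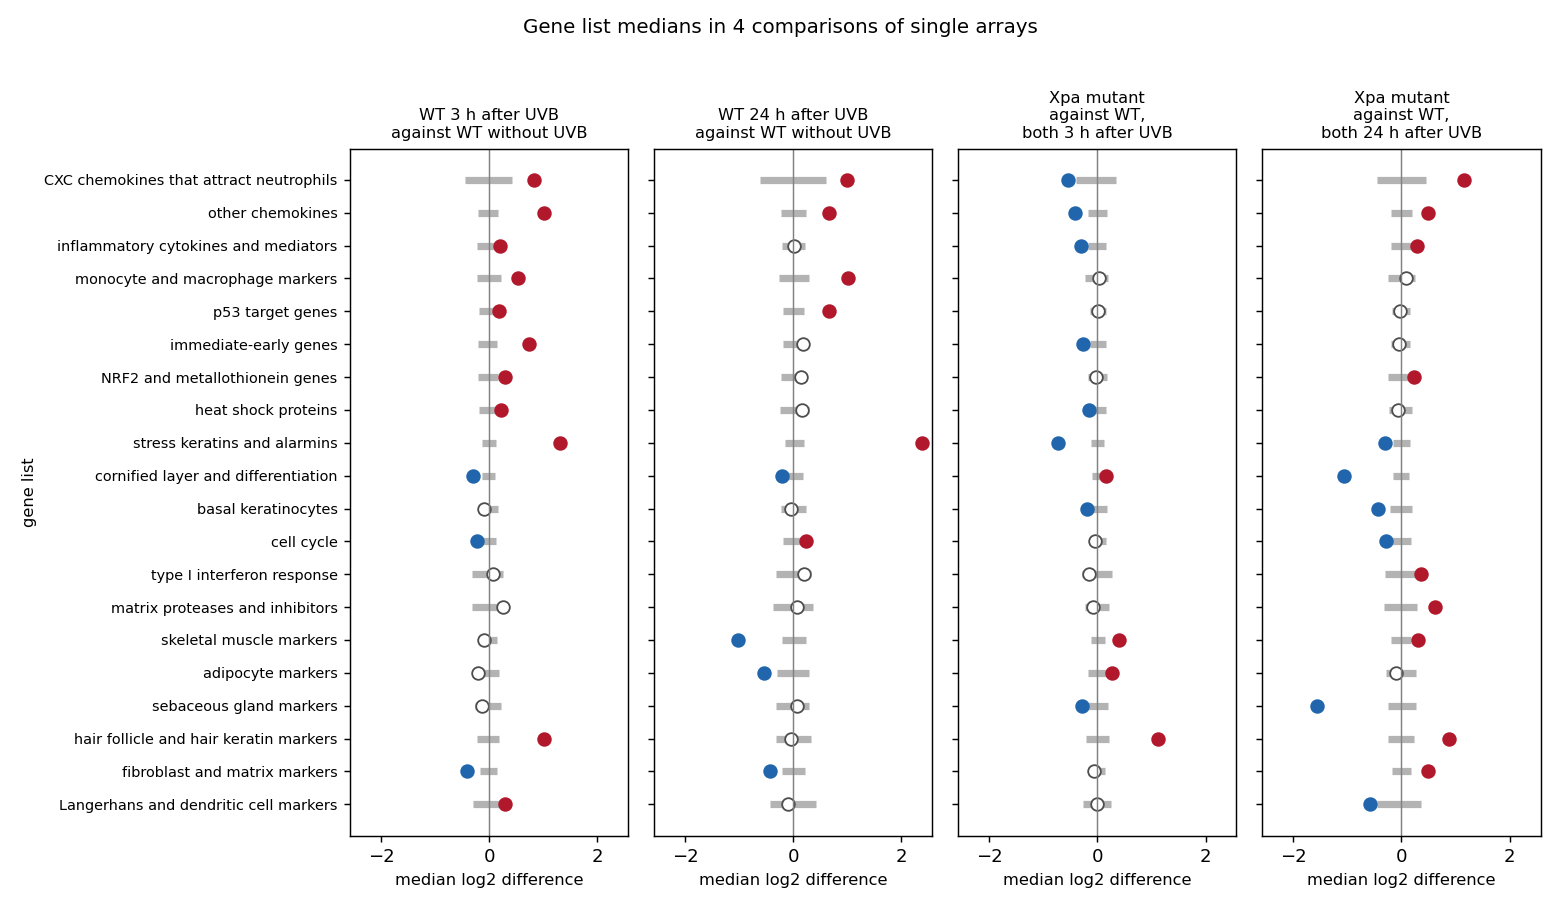
Median log2 difference of each gene list that stood apart in at least 1 of the 4 comparisons (x axis, log2; y axis, gene lists). Filled red and blue points stand apart upwards and downwards, open points do not, and grey bars span the range of 10000 random lists within which a list does not stand apart. Chemokine medians lie below 0 in the mutant at 3 h (-0.55 and -0.42) and above 0 at 24 h (1.16 and 0.50).

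The comparison of Xpa mutant with WT skin at 3 h sets levels after UVB side by side. Since unirradiated mutant skin was not analysed here, a different response to UVB cannot be told apart from a difference present before it. Of 22 stress keratins and alarmins 6 were at least 2-fold lower on the mutant array, and 10 of 19 hair follicle and hair keratin genes were higher. Few inflammatory genes passed 2-fold, and Cxcl1 (1.46-fold), Cxcl2 (1.86-fold) and Il6 (1.85-fold) were below WT by less than that. The lymphoid chemokine Ccl19 and the keratinocyte chemokine Ccl27a were lowest, 3.81-fold and 3.45-fold. The keratin-associated proteins of the hair shaft Krtap21-1 and Krtap19-2 were higher, 8.57-fold and at least 10.1-fold.

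Of 6862 genes compared, 77 were at least 2-fold higher and 68 lower (robust SD 0.28), and for 59 and 57 of these the dimmer array was below background. The authors' deposited table gave 209 and 224, and genes above background on both arrays 18 and 11. This comparison and that of WT at 3 h with unirradiated skin share the WT array at 3 h with opposite sign, so a chance high value there raises a gene in the latter and lowers it in the former.

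The stress keratins and alarmins had a median of -0.73 in the mutant at 3 h (percentile 0) with 0 higher, and the 6 lower genes included Sprr2e at 3.02-fold and Sprr2i and Sprr2g at least 2.20-fold and 2.34-fold. Of 16 other chemokines 0 were higher and 2 lower (median -0.42, percentile 0). The 2 lower genes, Ccl19 and Ccl27a, lie near each other on the chromosome of Xpa in the GRCm38.p6 gene table. Without them the other 14 had a median of -0.41 (percentile 0.01), and 11 of them lay below 0. The 3 CXC members had a median of -0.55 (percentile 0.42), 19 cytokines and mediators of -0.29 (percentile 0.03), 21 immediate-early genes of -0.27 (percentile 0.04) and 14 heat shock genes of -0.16 (percentile 2.25), each with 0 members past 2-fold. The cytokine median over genes above background on all 5 arrays was -0.09, and with no filter on dim probes the heat shock median was -0.12, neither of them apart. Of the 3 CXC members Cxcl1 and Cxcl2 were lower and Pf4 was 1.40-fold higher. Over the 6 CXC members above background on any of the 5 arrays, the median level relative to unirradiated skin was 0.45 in the mutant and 0.29 in WT. Only 3 of those were above background on either array at 3 h, so these levels rest partly on dim probes. Icam1 was 1.77-fold lower, Il1b at least 1.25-fold, the stress factor gene Atf3 at least 1.17-fold and Hsp90aa1 1.46-fold. Neutrophil and macrophage markers had medians of 0.03 and 0.03 (percentiles 53.04 and 56.24). The p53 targets had a median of 0.01 (percentile 44.98), with Cdkn1a 1.15-fold lower.

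Among 19 hair follicle and hair keratin genes 10 were at least 2-fold higher in the mutant at 3 h and 0 lower (median 1.13, percentile 100), among them the hair shaft keratin genes Krt86 and Krt33a at 4.44-fold and 4.42-fold. Krtap1-5 and Krtap15 were at least 4.25-fold and 4.08-fold higher. Skeletal muscle markers had a median of 0.40 over 18 genes (percentile 100) and adipocyte markers of 0.28 over 10 (percentile 99.9). In both lists 0 members passed 2-fold. The muscle enzyme Ckm was 1.91-fold and the fat and liver enzyme Pck1 1.95-fold higher. Apobec2, a muscle protein of the cytidine deaminase family, was at least 3.13-fold higher. Sebaceous gland markers had a median of -0.28 over 8 genes (percentile 0.34; 0.18 over those above background on all 5 arrays), cornified layer genes of 0.15 over 29 (percentile 99.5) and basal keratinocyte genes of -0.18 over 13 (percentile 1.65). The cornified layer median was 0.10 and the basal keratinocyte median -0.13 with no filter on dim probes, neither of them apart. The epidermal regulator Trp63 was 1.76-fold lower. Polr1b and the zinc finger gene Zfp947 were at least 1.37-fold and 1.21-fold lower.

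At 24 h the same comparison again sets levels after UVB side by side, with the same limit. The medians of the chemokine and the fibroblast and matrix lists were higher on the mutant array than on the WT array, while many cornified layer and sebaceous gland genes were at least 2-fold lower. Cxcl1 was 1.90-fold higher, Cxcl2 at least 2.15-fold, Il1b at least 1.77-fold and Il6 at least 1.87-fold. Saa3, an acute phase gene on the stress keratin and alarmin list, was 5.15-fold and the protease inhibitor Timp1 at least 4.08-fold higher. The cornified envelope genes Lce1c and Lce1b were lower, Lce1b 8.10-fold and Lce1c, below background in the mutant, at least 9.24-fold.

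Of 7103 genes compared, 114 were at least 2-fold higher and 189 lower (robust SD 0.34), and for 75 and 90 of these the dimmer array was below background. The authors' deposited table gave 295 and 404, and genes above background on both arrays 39 and 99. This comparison and that of WT at 24 h with unirradiated skin share the WT array at 24 h with opposite sign. A value particular to that array thus moves a gene in opposite directions in them, and Krt16, Gtf2h5 and Col1a1 are among the genes that did so. The Y-linked gene Eif2s3y was above background only on the mutant array at 24 h, at least 1.89-fold higher than on the WT array.

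**Figure D2:**
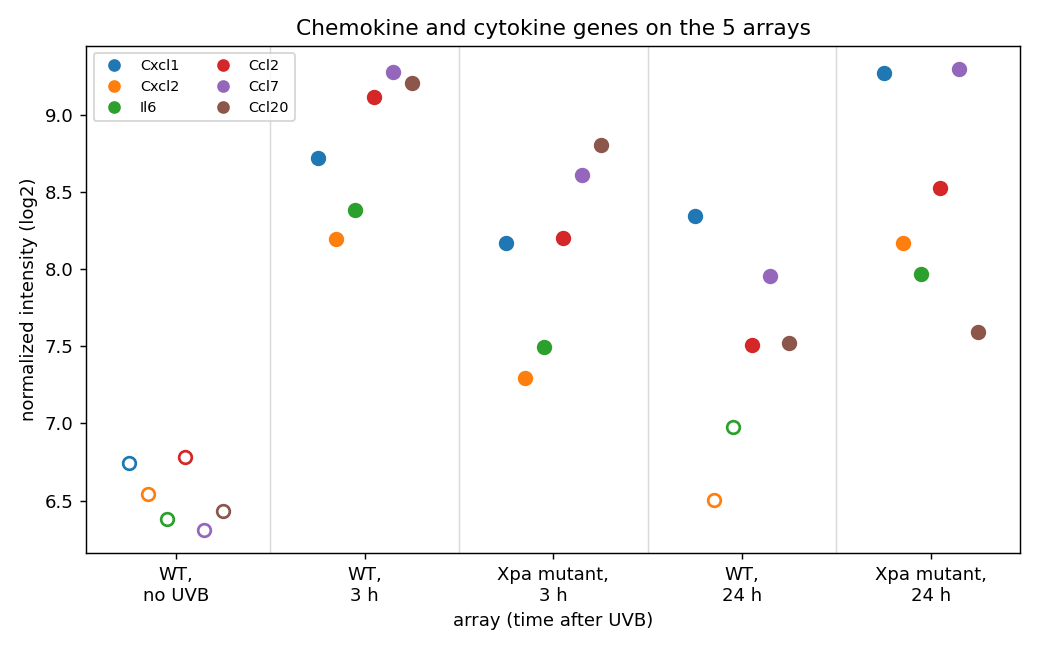
Normalized intensity (log2, y axis) of 6 chemokine and cytokine genes on each of the 5 arrays (x axis), 1 point per gene and array, filled where the probe was above background and open where it was not. Cxcl1 lies at 8.35 on the WT array and 9.27 on the mutant array at 24 h.

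Of 5 CXC chemokines 4 were at least 2-fold higher in the mutant at 24 h and 0 lower (median 1.16, percentile 100). They included the platelet genes Ppbp, at least 2.92-fold, and Pf4, and also Cxcl3, at least 1.80-fold, but not Cxcl1, which stayed under 2-fold. With 3 of the 5 genes at their bounds the median was 1.06. Among 13 other chemokines 4 were higher and 1 lower (median 0.50, percentile 100), with Ccl6 2.64-fold and Ccl7 2.53-fold higher and Ccl27a 3.70-fold lower. Among genes above background on all 5 arrays the median of the other chemokines was 0.15. Over 20 cytokines and mediators 2 were higher and 1 lower (median 0.29, percentile 99.9). Il19 was at least 1.64-fold higher, and Il1f5, which encodes an antagonist of the interleukin 36 receptor, was 2.30-fold lower. Macrophage markers had a median of 0.08 over 9 genes (percentile 76.1), although Cd14 was 2.28-fold higher. Neutrophil markers had a median of 0.20 over 6 genes (percentile 81.5), with Retnlg at least 2.16-fold higher. Interferon response genes had a median of 0.36 over 12 (percentile 98.9), with Oas2, an antiviral enzyme, at least 1.38-fold higher, and 12 NRF2 and metallothionein genes of 0.22 (percentile 97.6), with Mt1 3.42-fold and Mt2 2.52-fold higher. Over genes above background on all 5 arrays the medians of the cytokines (0.16), interferon response genes (0.22) and NRF2 and metallothionein genes (0.17) no longer stood apart, nor did that of the other chemokines. The CXC list kept fewer than 3 genes under that filter and so had no median.

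**Figure D3:**
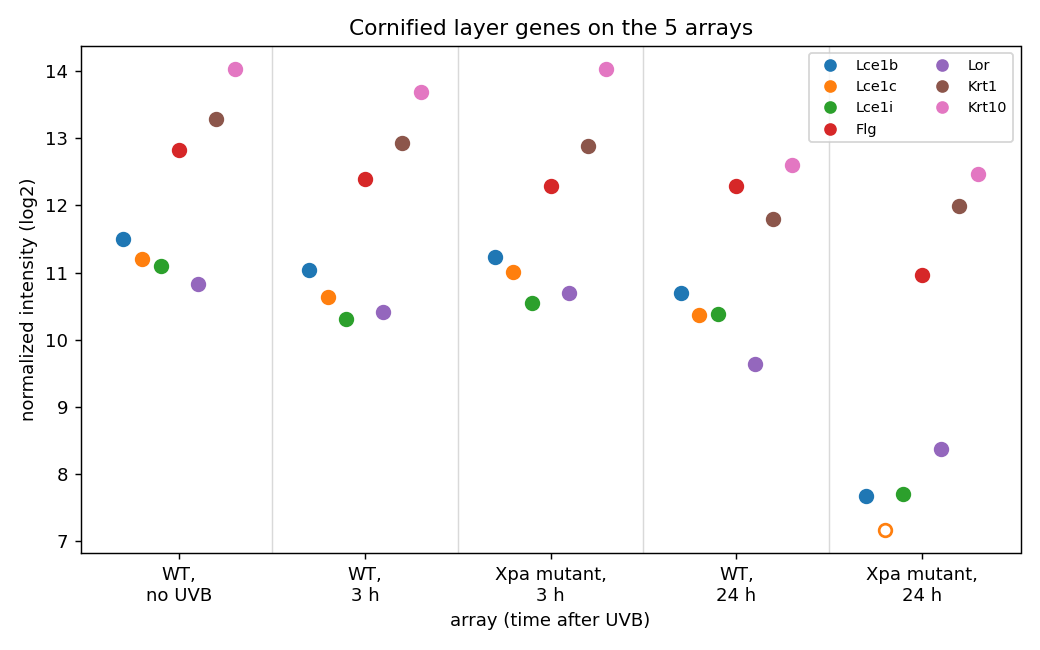
Normalized intensity (log2, y axis) of 7 cornified layer genes on each of the 5 arrays (x axis), filled where the probe was above background and open where it was not. Lce1b differs by -3.02 between the mutant and WT arrays at 24 h and Krt1 by 0.19.

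Among 33 cornified layer genes 18 were at least 2-fold lower in the mutant at 24 h and 0 higher (median -1.07, percentile 0), including Lce1i at 6.39-fold. Lce1l was at least 3.15-fold lower. The probes of the closely related Lce genes may read each other's transcripts, and the 20 other members had a median of -0.76. Krt1 and Krt10, keratins of the layers where differentiation begins and chosen here after their values were seen, differed by 0.19 and -0.14. Basal keratinocyte genes had a median of -0.44 over 14 with 0 past 2-fold (percentile 0.01), and Krt14 was 1.88-fold lower. Stress keratins and alarmins split, with 4 of 25 higher and 7 lower (median -0.30, percentile 0.05). Saa3 was higher, while Krt6b and Krt16 were 2.91-fold and 2.77-fold lower. Of 8 sebaceous gland markers 6 were lower and 0 higher (median -1.56, percentile 0), with the lipid enzymes Elovl3 and Elovl6 4.04-fold and 3.67-fold and Far2 at least 3.79-fold lower. Pgf, a placental growth factor of the VEGF family, and the cytochrome P450 Cyp2g1 were at least 7.52-fold and 5.86-fold lower.

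Connective tissue genes were higher on the mutant array at 24 h, with the arrays aligned on most probes and not on the spiked controls. Of 18 fibroblast and matrix markers 3 were at least 2-fold higher and 0 lower (median 0.49, percentile 100), with Sparc, a matrix glycoprotein, 2.99-fold, Col1a2 2.93-fold and Col1a1 2.10-fold. Relative to the unirradiated WT array the median of this list was -0.41 and -0.43 on the WT arrays at 3 h and 24 h, -0.42 on the mutant array at 3 h and 0.00 on the mutant array at 24 h. Matrix proteases and inhibitors had 4 of 9 higher and 0 lower (median 0.62, percentile 100), with the macrophage elastase gene Mmp12 at least 1.62-fold and the urokinase receptor gene Plaur at least 1.70-fold higher. Skeletal muscle markers had a median of 0.30 (percentile 99.9) and adipocyte markers of -0.10 (percentile 21.1). Hair follicle genes were higher, 5 of 10 by at least 2-fold (median 0.89, percentile 100), with Krt73 at least 2.44-fold and Krt25 2.70-fold. The hair median was 0.52 with dim genes at their bounds, and 0.066, no longer apart, over genes above background on all 5 arrays. Apobec2 was at least 5.14-fold and Mup1, a major urinary protein, 5.69-fold higher. Cell cycle genes had a median of -0.28 over 21 with 0 past 2-fold (percentile 0.17; -0.038 and no longer apart under that filter), and p53 targets of -0.02 over 22 (percentile 43.3), with Cdkn1a 1.19-fold higher. Of 16 nucleotide excision repair genes 2 were lower and 0 higher (median -0.18, percentile 8.20), Xpa itself and Gtf2h5, at 2.22-fold.

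Between the mutant comparisons at 3 h and 24 h, 14 of 6180 genes compared in both were at least 2-fold higher at both times and 3 lower, where independent lists would share 0.51 and 1.21.

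The change from 3 h to 24 h in the mutant, set against that in WT, is the difference between the mutant comparisons at the 2 times. By this measure the change was higher on the mutant arrays than on the WT arrays by the medians of the chemokine, cytokine and fibroblast and matrix lists, and lower by that of the cornified layer genes. Among the highest genes the log2 difference was 2.72 for Mt1 and 2.53 for Saa3, and among the lowest -3.21 for Lce1b and -3.19 for Lce1m, all above background on the 4 arrays. Cxcl1, also above background on all 4, differed by 1.47. Timp1, Cxcl2 and Ddhd2, a phospholipase gene, were among the highest too, and Lce1c, Lce1l and Pgf among the lowest. These 6 genes were below background on at least 1 of the arrays, as were Il1b and Il6, so no value is given for them.

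Of 7785 genes compared, 316 were at least 2-fold higher and 414 lower (robust SD 0.50), and for 231 and 295 of these at least 1 of the 4 arrays was below background. The authors' deposited table gave 675 and 812, and genes above background on all 4 arrays 85 and 119. Each value adds the noise of 4 arrays, and with 1 array per group the difference was not tested.

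The CXC list had a median of 1.67 over 5 genes with 4 higher, and other chemokines of 0.80 over 16 with 6 higher and 0 lower (percentile 100 for both), with Ccl7 at 2.00 and Ccl2 at 1.93. Cytokines and mediators had a median of 0.40 (percentile 99.8), immediate-early genes of 0.41 (percentile 100), p53 targets of 0.30 (percentile 99.5, with 2 of 22 higher and 1 lower), NRF2 and metallothionein genes of 0.31 (percentile 98.4, with 2 of 14 higher), interferon response genes of 0.46 (percentile 99.0) and matrix proteases of 0.56 (percentile 99.5). The p53 median was -0.021 under background subtraction with a floor. Stress keratins and alarmins had 8 of 25 higher and 3 lower (median 0.44, percentile 100), with the alarmin S100a8 at 2.18. The median of this list over genes above background on all 5 arrays was -0.12. Of 18 fibroblast and matrix markers 5 were higher and 0 lower (median 0.76, percentile 100). Cornified layer genes had 17 of 33 lower and 1 higher (median -1.04, percentile 0), sebaceous gland markers 5 of 8 lower (median -1.51, percentile 0) and hair follicle genes 7 of 19 lower and 1 higher (median -0.55, percentile 0.08). Nucleotide excision repair genes had a median of -0.38 over 16 (percentile 1.27), basal keratinocyte genes of -0.38 (percentile 0.79) and B cell markers of -0.71 over 4 (percentile 1.06). Over genes above background on all 4 arrays the medians of hair follicle genes (-0.10), repair genes (-0.048), NRF2 and metallothionein genes (0.22), interferon response genes (0.23), matrix proteases (0.37) and stress keratins and alarmins (0.028) no longer stood apart. Over those above background on all 5, nor did the other chemokines (0.18), and with the mean of a gene's probes nor did basal keratinocyte genes (-0.21) or B cell markers (-0.19).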

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

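All tests in this part were chosen only after the result was seen. Gene groups whose median differed in sign between the mutant comparisons at 3 h and 24 h stood out. The CXC chemokines had a median log2 difference between mutant and WT of -0.55 at 3 h and 1.16 at 24 h, the other chemokines of -0.42 and 0.50, the cytokines and mediators of -0.29 and 0.29, and the cornified layer genes of 0.15 and -1.07. The members above background differ between the times, 3 CXC genes at 3 h and 5 at 24 h. Over the same 6 CXC genes the median level relative to unirradiated skin was 0.45 in the mutant at 3 h and 0.29 in WT. Only 3 of these genes were above background on either array at 3 h, so these levels rest partly on dim probes. With 1 array per group the differences between the times were not tested. The cytokine medians over genes above background on all 5 arrays were -0.090 at 3 h and 0.16 at 24 h, and the other chemokines had 0.15 at 24 h, none of them apart from random lists. The CXC list had no median under that filter, since fewer than 3 of its genes passed, so it could not be checked in this way. The cornified layer median at 3 h was 0.10, no longer apart, with no filter on dim probes.

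The median of the other chemokines was below 0 in the mutant at 3 h, with 2 of 16 genes at least 2-fold lower. It was above 0 at 24 h, with 4 of 13 higher and 1 lower. The CXC list at 3 h rested on 3 measured genes (median -0.55), with Cxcl1 and Cxcl2 lower, Pf4 higher and 0 past 2-fold. At 24 h its genes past 2-fold included the platelet genes Ppbp and Pf4 but not Cxcl1. Under 5 other corrections and scalings both signs held, and the smallest gap between the 24 h and 3 h medians was 0.76, so the choice among these is an unlikely source. All 5 align the arrays on most probes, however, and none on the spiked controls. The shifts of those controls were -0.31 on the WT array and 0.27 on the mutant array at 24 h. A scaling by them was not tried, and it would lower mutant values relative to WT values at 24 h. Normalization therefore stays open as a source, also for the fibroblast and matrix and the muscle medians above 0 there. More of the macrophages already present in skin are unlikely too, since of the 6 macrophage markers above background on all 5 arrays the highest difference at 24 h was 0.14, in C1qb, although Cd14, below background on 2 arrays and so not among them, was 2.28-fold higher. More neutrophils cannot be told apart from a response of the skin cells, because only 6 of 25 listed neutrophil markers were above background, with a median of 0.20. The genotype, the animals and their pieces of skin stay open and untested.

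The cornified layer genes were lower in the mutant at 24 h. Cross-reading between Lce probes is unlikely to account for the whole group, since without the 13 Lce genes, whose median was -2.26, the other 20 had a median of -0.76 at percentile 0 of random lists. A smaller share of epidermis may contribute, since the basal keratinocyte median was -0.44 while fibroblast and muscle markers had medians of 0.49 and 0.30, but it would lower all keratinocyte genes alike, and 18 of 33 cornified layer genes lay below the lowest basal marker. The sex of the animals cannot be told apart from the genotype, since a Y-linked gene was above background on 1 array and that array is the mutant at 24 h. The genotype remains a candidate explanation, untested.

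Hair follicle and hair keratin genes were higher at 3 h than without UVB, and higher in the mutant than in WT at both times, but over genes above background on all 5 arrays the medians in WT at 3 h (0.26) and in the mutant at 24 h (0.066) no longer stood apart. Deeper tissue in the sample is an unlikely source for the WT array at 3 h, since the skeletal muscle markers had a median of -0.10 there. For the mutant at 3 h it may contribute, since the muscle markers had a median of 0.40 and the adipocyte markers of 0.28. Whether the mutant sample at 24 h held more whole follicles with their glands cannot be told. The sebaceous gland markers had a median of -1.56 there, which lower expression within the glands could also give. The phase of the hair cycle in each piece of skin and the genotype stay open and untested.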

How the results depend on the processing

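Of the alternatives, the filter for genes above background on every array compared, quantile normalization without the mutant array at 24 h and list medians with dim genes at their bounds were chosen after seeing the data. Over all alternatives, the 10 counts of genes moved by more than 1.5 times in 76 recomputations and stayed within that in 50. The 67 list medians that stood apart kept their side of the percentile limits in 652, no longer stood apart in 65 and changed sign in 9. Single named genes moved by more than the limit in 537 recomputations and stayed within it in 3591. These totals include the thresholds of 1.5-fold and 3-fold, which change the counts by their nature (10 moved at each). They also hold the authors' values 2 times, as their table and as the series' matrix. The totals therefore do not measure how much the processing matters. Cyclic loess kept all 10 counts and 67 medians, and normalization without the mutant array at 24 h left the 6 counts it could give within 1.5 times. With dim genes at their bounds, 51 of 51 list medians of the 4 comparisons between arrays kept their sign. A bound shrinks a gene's difference but cannot reverse it, so the kept signs are not a check of direction. The sizes could change, and 3 medians moved by more than 1.5 times. These were the other chemokines (0.58) and hair genes (0.55) in WT at 3 h, and hair genes (0.52) in the mutant at 24 h. Signal over background limited most results, since a majority of the genes past 2-fold in each comparison were below background on an array involved. Few genes had another probe above background to check them. Of those past 2-fold, 8 of 252 had such a probe in WT at 3 h, with the opposite sign in 2, and for WT at 24 h, the mutant at 3 h, the mutant at 24 h and the difference of changes 12 (3 opposite), 2 (1), 8 (2) and 33 (7). The series' matrix holds the authors' values, so it gave the same numbers as their table. Apart from changes that follow from which genes a filter or threshold admits, the cause was not tested.

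Counts follow as higher and lower genes at 2-fold, for WT at 3 h, WT at 24 h, the mutant at 3 h, the mutant at 24 h and the difference of changes. Without background correction they were 86 and 23, 91 and 78, 40 and 12, 58 and 103, and 130 and 203. In the authors' table they were 333 and 310, 400 and 398, 209 and 224, 295 and 404, and 675 and 812. Among genes above background on all 5 arrays they were 49 and 8, 61 and 56, 3 and 9, 28 and 96, and 72 and 119. Among genes above background on every array compared they were 50 and 11, 64 and 68, 18 and 11, 39 and 99, and 85 and 119. At 1.5-fold they were 470 and 454, 612 and 637, 271 and 349, 472 and 580, and 1020 and 1088. At 3-fold they were 48 and 12, 47 and 19, 23 and 6, 18 and 36, and 72 and 87. With no filter on dim probes, 148 genes were lower in WT at 3 h, 143 higher and 122 lower in the mutant at 3 h, and 668 higher and 880 lower in the difference of changes. Background subtraction with a floor gave 38 lower genes in the mutant at 3 h.

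The list medians that changed sign follow. Over genes above background on all 5 arrays, the other chemokines had a median of -0.044 in WT at 3 h and -0.20 in WT at 24 h, where the filter leaves out those that were dim without UVB. Under that filter the stress keratins and alarmins had -0.12 in the difference of changes and the sebaceous markers 0.18 in the mutant at 3 h. Over genes above background on every array compared, the other chemokines again had -0.044 and -0.20, and the cytokines -0.0061 in WT at 3 h. The CXC list had no median over genes above background on all 5 arrays, as fewer than 3 of its genes passed. Over genes above background on every array compared, the same held in WT at 3 h and 24 h, the mutant at 24 h and the difference of changes. With no filter on dim probes the CXC chemokines had -0.040 in WT at 24 h. Background subtraction with a floor gave the p53 targets -0.021 in the difference of changes.

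The medians that kept their sign but no longer stood apart follow. Over genes above background on all 5 arrays, these were cytokines 0.15 and Langerhans markers 0.18, cell cycle -0.15 and hair 0.26 in WT at 3 h. They were cytokines -0.090 and basal keratinocyte genes -0.067 in the mutant at 3 h. In the mutant at 24 h they were other chemokines 0.15, cytokines 0.16, NRF2 genes 0.17, cell cycle -0.038, interferon 0.22 and hair 0.066. In the difference of changes they were other chemokines 0.18, repair genes -0.048, NRF2 genes 0.22, interferon 0.23, proteases 0.37 and hair -0.27. Over genes above background on every array compared, they were p53 targets 0.14, cell cycle -0.15 and Langerhans markers 0.18 in WT at 3 h, and cytokines 0.16, NRF2 genes 0.17 and interferon 0.14 in the mutant at 24 h. In the difference of changes they were repair genes -0.048, NRF2 genes 0.22, stress keratins 0.028, interferon 0.23, proteases 0.37 and hair -0.10.

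With no filter on dim probes, the medians that no longer stood apart were CXC 0.10, other chemokines 0.12 and Langerhans markers 0.18 in WT at 3 h, and other chemokines 0.15 in WT at 24 h. In the mutant at 3 h they were heat shock -0.12, cornified layer 0.10 and basal keratinocyte genes -0.13, and at 24 h cytokines 0.11, interferon 0.14 and Langerhans markers -0.11. In the difference of changes they were p53 targets 0.058, repair genes -0.055, NRF2 genes 0.22, interferon 0.10, proteases 0.24 and B cell markers -0.39. Without background correction, they were p53 targets 0.11 in WT at 3 h, and in the difference of changes p53 targets 0.071, repair genes -0.21, NRF2 genes 0.24 and interferon 0.26. In the authors' table, they were Langerhans markers 0.30 in WT at 3 h, and NRF2 genes 0.21 and interferon 0.53 in the difference of changes. Background subtraction with a floor gave cell cycle -0.23 in WT at 3 h and B cell markers -0.39 in the difference of changes. Median scaling gave p53 targets 0.14 in WT at 3 h. The mean of a gene's probes gave, in the difference of changes, repair genes -0.28, basal keratinocyte genes -0.21 and B cell markers -0.19. Against random lists not matched on expression, heat shock (-0.16) and basal keratinocyte genes (-0.18) in the mutant at 3 h no longer stood apart.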

Other observations

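The tests of neighbouring genes and of the Y-linked gene in this part were chosen only after the result was seen, while that of very long genes was not. Genes of the circadian clock, growth factors and resident immune cells add to the picture in WT skin. At 24 h the clock output factors Tef and Hlf were lower than without UVB, 2.21-fold and at least 1.28-fold. The 8 clock genes together had a median of 0.03 (percentile 53.6), and the 7 at 3 h of -0.11. Of the EGF receptor ligands, Hbegf was at least 3.08-fold and Areg at least 1.49-fold higher at 3 h, and Hbegf at least 2.30-fold higher at 24 h. With 2 members above background the list has no median in WT, and between mutant and WT it had -0.21 at 3 h and 0.22 at 24 h. Langerhans and dendritic cell markers had a median of 0.29 in WT at 3 h over 6 genes (percentile 97.7), with Cd207, the langerin gene, at least 1.33-fold higher, but of 0.18, no longer apart, with no filter on dim probes.

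In the mutant at 24 h, Langerhans and dendritic cell markers had a median of -0.58 against WT over 5 genes (percentile 1.22). Of these 1 was at least 2-fold lower and 0 higher. That median was -0.11 and no longer stood apart with no filter on dim probes. The antigen-presenting class II genes H2-Eb1 and H2-Aa were 2.29-fold and 1.80-fold lower. The 3 B cell markers had a median of -0.53 (percentile 3.17), with the immunoglobulin joining chain gene Jchain 2.24-fold lower. Mast cell markers had a median of 0.19 over 6 genes (percentile 91.8), endothelial markers of 0.39 over 5 (percentile 94.1) and housekeeping genes of -0.02 over 13 (percentile 50.9), none of them apart from random lists. T cell, melanocyte, red blood cell and sex-chromosome markers had too few members above background for a median.

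Unrepaired DNA lesions that block transcription were asked to show as lower expression of very long genes in the mutant. The 109 genes were listed by hand as long ones, without measured gene lengths, which limits this check. Of them 41 were compared at 3 h, with a median of 0.05 at percentile 79.3 of random lists, and 43 at 24 h, with a median of 0.01 at percentile 59.9. Neither comparison showed lower long genes, and unirradiated Xpa mutant skin was not analysed here.

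A run of neighbouring genes was lower in the mutant at both times, with Ccl27a in it and Ccl19 close by. Among 7674 windows of 6 measured genes in the order of the GRCm38.p6 gene table, that from Rpp25l to Ccl27a had the lowest mean, taking for each gene the difference nearer 0 of both times, -0.81, and the lowest on another chromosome -0.43. Of its genes, chosen here after their values were seen, Rpp25l differed by -1.13 at 3 h and -1.02 at 24 h, Il11ra1 by -0.93 and -0.48, and Ccl27a by -1.79 and -1.89. With 20 measured genes between it and Xpa, the window lies on the chromosome of the targeted gene. Over the 100 measured genes nearest Xpa, the size of difference shared by both times averaged 0.18, at percentile 99.6 of all windows of 100 genes. The run from Rpp25l to Ccl27a is among these 100 genes, so that average is not separate from it. On the same chromosome Nipsnap3b (2.00 and 1.39) and Mup1 (1.82 and 2.51) were higher. DNA linked to Xpa that differs between the mutant and the WT animals, such as a strain difference carried along with the mutation, is a candidate explanation. It may account for the place of Ccl19 and Ccl27a among the lowest genes, which was not tested beyond this order of genes.

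The Y-linked gene Eif2s3y was above background on 1 array, the mutant at 24 h. Xist, expressed from the inactive X chromosome of females, had its lowest level there (6.41, below background), against 7.39 on the unirradiated WT array, 7.59 on the WT array at 3 h, 7.25 on the mutant array at 3 h and 7.12 on the WT array at 24 h. It was above background on 2 arrays, both WT. The other Y-linked genes listed, Ddx3y, Kdm5d and Uty, were not above background on any array. The values of Eif2s3y and Xist may reflect a male animal on the mutant array at 24 h and females on the others. The probes are dim, however, and the sex of the animals is not given in the sources used here.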
